A study of Mus musculus with 2 samples.

How the data were processed

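Gastrocnemius RNA of adult male 5xFAD/CAST mice, labelled as a cross, was profiled in 2 libraries. Per the labels' protocols, RNA was purified with a column kit for animal tissue, 300 ng entered a directional library kit, ribosomal RNA was reduced and ERCC spike-in RNA was added. Each library had 3 deposited tables on mm10 with the GENCODE M21 gene set: a gene table, an RSEM transcript table and a transcript table in the layout that kallisto writes, called here the kallisto-layout table. The aligner and the versions of the programs are not given in the sources used here. Per the file headers, the gene and RSEM transcript tables hold expected counts, in which a read that fits several genes is divided among them, together with TPM and a posterior SD of each count. The deposited estimated counts and TPM of the kallisto-layout table were summed per gene. In the deposited RSEM tables the effective length was the transcript length less 100.

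All 55536 gene identifiers of the gene table were matched to the M21 annotation, which gave symbols, gene types and mm10 coordinates. The kallisto-layout table had no entry for 86 of these genes, and they were taken as 0 there. Rows for 96 ERCC RNAs, phiX and 26248 short sequences named by number were left out of library sizes and ratios. ERCC and phiX together took 0.527% of expected counts in replicate 1 and 0.474% in replicate 2, and the short sequences had 1 and 0 counts. Gene totals were 35163970 and 35412240 expected counts. A symbol carried by several genes was taken as the gene of highest mean TPM within lists. Cyr61, Rn7sl1 and Norad are not symbols of this annotation and were left out of their lists.

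Both libraries formed 1 group, so levels were described as mean ± SD and no group comparison was made. Levels and shares used the deposited TPM. The contrast of replicate 2 with replicate 1 used expected counts rounded to whole numbers, TMM factors from edgeR 4.0.16 over genes with a mean count of at least 10, and a prior of 0.5 counts per library. Genes with a mean expected count of at least 100 entered the count of genes differing at least 2-fold, beside 100 simulations of counting error. Intervals of ratios are exact binomial 95% intervals on the 2 counts. Reads are not independent molecules, so these intervals cover counting error only. For each list of genes with a mean count of at least 10, the median log2 ratio was ranked among 10000 random lists of the same size matched on expression decile, which describes these libraries and is not a test. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept alone. Spike-in ratios were centred on their median and set beside genes of similar count. Reads were called divided among genes where the posterior SD exceeded 5% of the count in either library. Ratios of TPM used a pseudocount of 0.1.

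The 28 lists (17 gene lists and 11 marker lists) and the rule for named genes were fixed before the data were examined. Named genes are the 20 nuclear protein-coding genes of highest mean TPM, the 4 adult myosin heavy chains, per list the 3 members of highest TPM and any member with a mean count of at least 100 and a log2 ratio of at least 1 in size, the 10 highest and 10 lowest ratios between replicates among genes with a mean count of at least 100 and a symbol that neither starts with Gm nor ends in Rik, the 5 highest and 5 lowest ratios between quantifications and 17 genes with known alternative transcripts. Other members of the lists, Gm42742 and the mitochondrial pseudogenes were named after their values were seen, as were all genes of the lists added in the closing section. Some genes that the rule names are not reported here.

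Alternatives were DESeq2 1.42.0 size factors, library totals, spike-in totals, deposited TPM, other count minimums, another prior, the kallisto-layout table, other TPM minimums and each library alone. R 4.3.3, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The steps were tested on simulated libraries drawn from the real means of 14361 genes with 200 genes changed. For the contrast of replicates, simulated changes of 1.5-fold, 2-fold and 4-fold were recovered with a median log2 ratio of 0.55, 0.99 and 2.03, and 1 of 67, 32 of 67 and 66 of 66 such genes were counted at 2-fold, with 0 of the 14161 unchanged genes. For the list step, 7 of 200 unmoved lists fell outside the central 95% of random lists and 191 of 200 lists of 12 genes moved by 0.3 were found above it. A simulated biological coefficient of variation of 8% was recovered as 7.93%. Simulated genes varied independently with a single spread and without divided reads, so these rates do not extend to lists of genes that vary together.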

Results

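Total RNA was sequenced from the gastrocnemius, the large fast muscle of the calf, of adult male 5xFAD/CAST mice, labelled as a cross of 5xFAD with CAST, aged 8 to 10 months. 5xFAD mice carry mutant human transgenes, APP among them, and are used as a model of amyloid deposition in Alzheimer's disease, and CAST is an inbred strain derived from wild Mus musculus castaneus. The series held 1 group of 2 libraries, labelled biological replicates 1 and 2, which came from separate biosamples under a single donor entry. No second tissue, genotype or age was present, so the data describe which genes this muscle expressed and how far the 2 libraries lay apart. No p-value can be drawn from 1 library per side. Values given as mean ± SD are over n = 2 libraries throughout. The gene tables summed to 35350142 expected counts in replicate 1 and 35580757 in replicate 2. At least 1 TPM, the deposited length-scaled abundance, was reached by 11508 and 11240 of the 55536 annotated genes, of which 10468 and 10240 were protein coding.

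The contractile programme was that of fast muscle. The 13 fast fibre genes had a median of 7977 ± 331 TPM and the 11 slow fibre genes a median of 189 ± 16.6 TPM. Summed TPM of the fast list exceeded that of the slow list 48.6 ± 4.5 fold, a gap far larger than the spread between the libraries. Myh4, which encodes the IIb myosin heavy chain of the fastest glycolytic fibres, made up 89.0 ± 0.84% of the TPM of the 4 adult myosin heavy chain genes. Myh1 (the IIx chain) made up 5.74 ± 0.77%, Myh2 (the IIa chain) 3.78 ± 0.09% and Myh7 (the slow chain) 1.53 ± 0.01%. The fast share, the sum of Myh4, Myh1 and Myh2, was therefore 98.5 ± 0.01%. Myh2 (67171027 to 67197517), Myh1 (67200052 to 67224575) and Myh4 (67238029 to 67260446) lie side by side on the forward strand of chromosome 11 in mm10. Myh7 lies on chromosome 14 from 54970684 to 54994626.

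**Figure D1:**
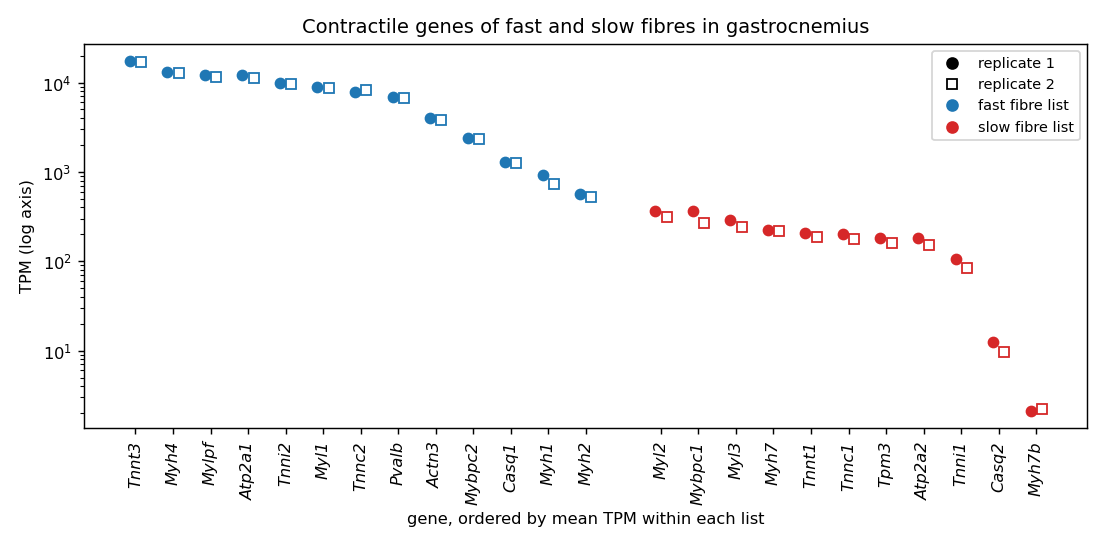
TPM (log axis) of each gene of the fast fibre list (blue) and the slow fibre list (red) in replicate 1 (filled circles) and replicate 2 (open squares). The fast genes run from 17065 TPM (Tnnt3) to 549 TPM (Myh2) in the mean, and every slow gene lies below them, from 338 TPM (Myl2) downward.

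Fast isoforms led every other part of the contractile apparatus as well. Tnnt3, the fast troponin T, reached 17065 ± 224 TPM against 197 ± 12.5 TPM for the slow Tnnt1. Tnni2, the fast troponin I, stood at 9708 ± 174 TPM and the slow Tnni1 at 94.6 ± 16.0 TPM. Atp2a1, the fast calcium pump of the sarcoplasmic reticulum, was at 11625 ± 674 TPM and the slow pump Atp2a2 at 168 ± 21.2 TPM. Pvalb, the calcium buffer parvalbumin, was at 6761 ± 155 TPM, and Actn3, the alpha-actinin of fast fibres, at 3944 ± 153 TPM. The most abundant slow transcripts were Myl2 (338 ± 37.4 TPM), Mybpc1 (316 ± 67.1 TPM) and Myl3 (267 ± 36.2 TPM). Among the 19 sarcomere genes shared by the fibre types, median 1391 ± 71.3 TPM, the highest were Acta1, skeletal alpha-actin, at 18503 ± 185 TPM, Ckm, muscle creatine kinase, at 16852 ± 760 TPM, and Tpm1 at 12340 ± 354 TPM. Acta1 had the highest mean TPM of all nuclear protein-coding genes. The 20 highest such genes also held Mylpf (11906 TPM), Myl1 (8770 TPM), Tnnc2 (7977 TPM), Neb (2978 TPM), Ttn (2389 TPM), Mybpc2 (2366 TPM) and Tcap (2122 TPM).

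Glycolysis genes stood above the nuclear genes of oxidative phosphorylation, and genes of the mitochondrial genome stood above both. The 15 glycolysis genes had a median of 1189 ± 4.0 TPM, led by Aldoa (10942 ± 421 TPM), Gapdh (4375 ± 169 TPM) and Pygm, the glycogen phosphorylase of muscle (3793 ± 95.8 TPM), with Eno3 at 3109 ± 22.3 TPM. The 26 nuclear genes of oxidative phosphorylation had a median of 366 ± 20.7 TPM, led by Atp5b (1400 ± 72.1 TPM), Cox8b (854 ± 62.2 TPM) and Atp5a1 (785 ± 55.6 TPM). The 16 genes of fatty acid uptake and oxidation had a median of 106 ± 10.8 TPM. Fabp3, the fatty acid binding protein of muscle, stood at 288 ± 0.06 TPM, Pdk4 at 177 ± 2.28 TPM and Hadhb at 164 ± 4.9 TPM. The 13 protein genes of the mitochondrial genome had a median of 5299 ± 20.2 TPM, led by mt-Co1 (16076 ± 1316 TPM), mt-Cytb (9897 ± 185 TPM) and mt-Nd1 (8697 ± 229 TPM). In the kallisto-layout table mt-Atp6 (18463 and 17561 TPM in replicates 1 and 2) stood above mt-Co1 (17409 and 16076 TPM).

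Genes of regeneration, wasting and stress were expressed at low to moderate levels. The developmental and regenerating fibre list had a median of 3.85 ± 0.30 TPM, with Myh8, the perinatal myosin, at 80.6 ± 6.4 TPM, Actc1 at 31.5 ± 1.41 TPM and Gadd45a at 12.5 ± 0.33 TPM. Atrophy and ubiquitin ligase genes had a median of 25.9 ± 0.21 TPM, led by Sqstm1 (269 ± 6.7 TPM), Bnip3 (95.7 ± 14.7 TPM) and Trim63, the muscle ligase MuRF1 (89.6 ± 15.3 TPM). Heat shock and unfolded protein genes had a median of 20.9 ± 6.5 TPM, with Cryab at 477 ± 76.5 TPM, Hspb7 at 123 ± 23.4 TPM and Hspb1 at 91.6 ± 2.72 TPM. Interferon response genes were at a median of 0.395 ± 0.064 TPM, and 5 of the 15 reached 1 TPM in both libraries. B2m (44.8 ± 3.9 TPM) and Bst2 (3.52 ± 0.77 TPM) were among the highest. Clock genes had a median of 9.69 ± 1.65 TPM, with Tef (82.7 ± 2.92 TPM) and Dbp (66.6 ± 0.42 TPM) highest. Immediate early genes had a median of 3.02 ± 0.22 TPM, with Nr4a1 (51.0 ± 0.59 TPM), Jun (25.5 ± 1.93 TPM) and Dusp1 (23.9 ± 2.28 TPM) highest. Ribosomal protein genes had a median of 224 ± 19.1 TPM (Rps14 357 ± 5.6 TPM, Rps24 293 ± 12.8 TPM and Rpl4 281 ± 15.6 TPM). Histone genes had a median of 2.75 ± 0.08 TPM (Hist1h1c 108 ± 2.05 TPM, Hist1h4c 35.3 ± 3.7 TPM and Hist1h2bc 26.2 ± 0.37 TPM). Together, 13 of the 28 lists had a median of at least 10 TPM.

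Mouse genes of the amyloid and tau pathways were present in the muscle, 17 of 18 at 1 TPM or more in both libraries, with a median of 20.6 ± 5.5 TPM. Bin1, a membrane-shaping protein of the T-tubules and a risk gene for Alzheimer's disease, was the highest at 296 ± 18.5 TPM. Psenen, a gamma-secretase subunit, was at 58.3 ± 5.8 TPM and Aplp2 at 54.9 ± 8.8 TPM. Mapt, which encodes tau, was at 37.9 ± 3.6 TPM, App at 35.1 ± 3.6 TPM, Apoe at 27.8 ± 3.3 TPM and Thy1 at 3.64 ± 0.39 TPM. The annotation listed mouse genes, so human transgene reads had no entry of their own, and reads of the APP transgene were not separated from those of mouse App.

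Markers of cells other than muscle fibres, and of the synaptic and myotendinous nuclei of fibres, had medians well below those of the contractile lists. Fibroblast markers had a median of 24.2 ± 1.48 TPM (Gsn 239 ± 12.7 TPM, Dcn 141 ± 5.7 TPM and Col1a2 47.9 ± 4.7 TPM). Adipocyte markers had a median of 12.5 ± 4.1 TPM (Car3, which muscle also expresses, 416 ± 49.9 TPM, Fabp4 107 ± 27.1 TPM and Cfd 28.9 ± 1.60 TPM). Endothelial markers had a median of 5.81 ± 0.78 TPM (Cdh5 14.8 ± 4.0 TPM, Egfl7 12.4 ± 0.47 TPM and Pecam1 11.8 ± 2.68 TPM). Smooth muscle and pericyte markers were at 4.17 ± 0.70 TPM (Rgs5 70.4 ± 16.0 TPM, Acta2 23.9 ± 4.8 TPM and Tagln 23.7 ± 0.55 TPM), and tenocyte markers at 4.59 ± 0.01 TPM (Fmod 46.8 ± 1.07 TPM, Thbs4 42.0 ± 3.3 TPM and Chad 14.4 ± 0.29 TPM). Erythroid genes had a median of 7.42 ± 0.49 TPM (Hbb-bs 125 ± 21.1 TPM, Hba-a1 117 ± 24.5 TPM and Hba-a2 77.7 ± 3.0 TPM). Leukocyte markers were at 2.40 ± 0.09 TPM (Lyz2 15.3 ± 1.43 TPM, Cd74 7.41 ± 0.37 TPM and C1qb 4.95 ± 0.06 TPM), satellite cell markers at 1.43 ± 0.18 TPM (Sdc4 13.7 and 10.3 TPM in replicates 1 and 2, Cdh15 7.95 ± 0.75 TPM and Chodl 2.06 ± 0.48 TPM) and Schwann cell and axon markers at 0.615 ± 0.007 TPM (Pmp22 9.63 ± 2.13 TPM and Mbp 8.09 ± 1.92 TPM). Genes of synaptic nuclei had a median of 8.21 ± 1.28 TPM (Prkar1a 40.3 ± 5.0 TPM, Musk 19.9 ± 3.2 TPM and Ache 11.1 ± 1.73 TPM), and genes of myotendinous nuclei 4.36 ± 0.24 TPM (Itgb1 74.8 ± 1.36 TPM, Lama2 17.1 ± 1.68 TPM and Tigd4 4.70 ± 0.27 TPM).

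Mitochondrial and structural RNAs took a large part of the libraries. Nuclear protein-coding genes held 75.5 ± 1.09% of expected counts, mitochondrial genes 16.0 ± 0.42%, pseudogenes 2.75 ± 0.05% and long noncoding and other genes 1.66 ± 0.17%. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 alone held 10.9 ± 0.43%. Rn7s1 and Rn7s2, the RNA of the signal recognition particle, held 3.68 ± 0.50% of counts and 24.8 ± 2.43% of TPM. The list of nuclear and structural noncoding RNAs had a median of 8.72 ± 1.56 TPM and was led by Rn7sk (13751 ± 972 TPM), Rpph1 (1864 ± 177 TPM) and Rmrp (1147 ± 32.1 TPM), with Malat1 at 677 ± 20.7 TPM. By TPM in place of counts the mitochondrial share was 19.5% and the pseudogene share 6.51%. In the kallisto-layout table they were 20.8% and 3.56% of TPM. The pseudogene class holds Gm28661, Gm28437 and Gm10925, paired below with mitochondrial genes, so the split between these classes depends on how reads were assigned.

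The 2 replicates agreed closely, and the few genes that stood apart included regulators of cytokine signalling, retinoic acid breakdown and transcription. Of 9741 genes with a mean expected count of at least 100, 98.8% lay within 1.5 fold of equality and 29 differed at least 2-fold, 16 higher and 13 lower in replicate 2. Counting error alone gave 0 such genes in 100 simulations. For 21 of the 29, the deposited posterior SD of the count exceeded 5% of the count in a library, a sign that reads were divided among similar genes. The other 8 included Cish, Utp14b, Kcnf1, Socs2 and Ccbe1, higher in replicate 2, and Cyp26b1 and Nr4a3, lower in replicate 2. The common biological coefficient of variation, the spread beyond counting error, was 7.71%. It was 5.95% without genes of divided reads and 8.57% with library totals, so part of it comes from how reads were divided. Whether the libraries came from separate animals is not given in the sources used here. Across all 55536 genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.995 and Spearman's rho 0.924. The spread between the libraries exceeded counting error, with a chi-square per degree of freedom of 11.6 over 9460 genes without divided reads, which does not separate technical from biological spread.

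Cish (ENSMUSG00000032578.7, chromosome 9, 107296026 to 107302784), a cytokine-induced inhibitor of JAK-STAT signalling, had the highest ratio of the 8 genes. It had 69 expected counts in replicate 1 and 901 in replicate 2, a log2 ratio of 3.75 with an exact binomial 95% interval of 3.40 to 4.13. Socs2 (ENSMUSG00000020027.18, chromosome 10, 95385362 to 95417180), from the same family of signalling inhibitors, had a log2 ratio of 1.10 (0.82 to 1.39). Kcnf1, a potassium channel subunit, had a log2 ratio of 1.43, Utp14b 1.63 and Ccbe1 1.03. Cyp26b1 (ENSMUSG00000063415.12, chromosome 6, 84571414 to 84593908), which degrades retinoic acid, had 482 and 119 counts and a log2 ratio of -1.96 (-2.27 to -1.67). Nr4a3, an orphan nuclear receptor induced by muscle activity, had a log2 ratio of -1.18 (-1.49 to -0.88). The next lowest unshared genes were Zdhhc23 at -0.88, Lep, the adipocyte hormone leptin, at -0.86 and Rgs4 at -0.86. The intervals cover counting error only, and a difference between 2 libraries has no replicate check.

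**Figure D2:**
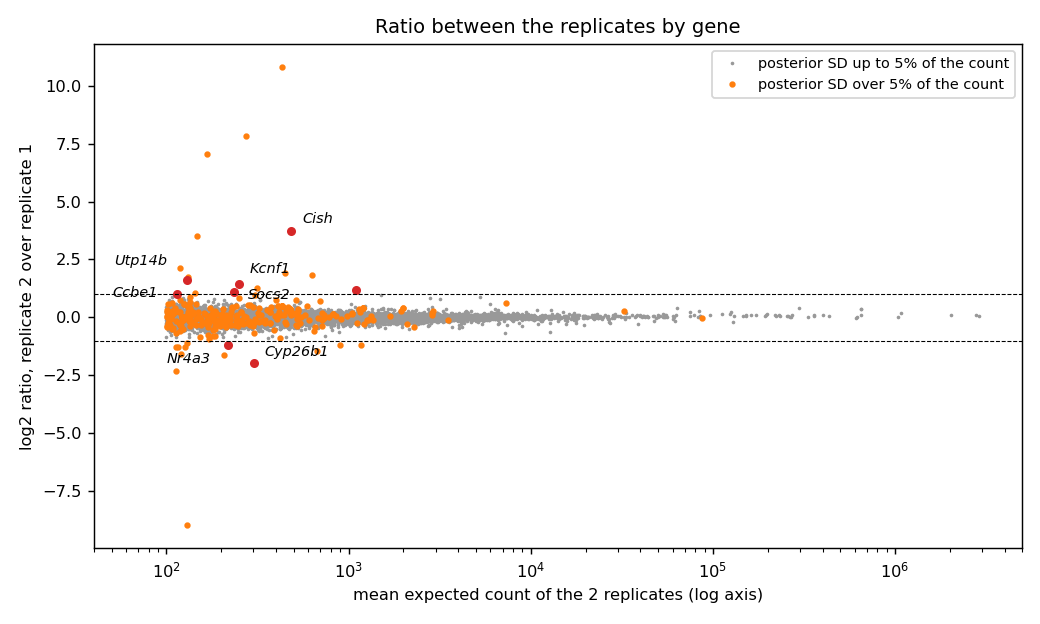
Log2 ratio of replicate 2 over replicate 1 against mean expected count (log axis) for the 9741 genes with a mean count of at least 100. Orange points are genes whose posterior SD exceeds 5% of the count, dashed lines mark 2-fold, and red points, most of them named, are the 8 genes beyond 2-fold without divided reads, from Cish at 3.75 to Cyp26b1 at -1.96.

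Among the genes with divided reads, some ratios held in the kallisto-layout table and others did not. Pagr1a, on chromosome 7 and overlapping Gm42742, had 259 counts in replicate 1 and 0 in replicate 2, while Gm42742 had 24 and 270, and their log2 ratios in the kallisto-layout table were -8.55 and 1.61. The gene listed as ENSMUSG00000102976.6 and that listed as ENSMUSG00000116275.1, which share the symbol Zc3h11a and the same stretch of chromosome 1, had log2 ratios of 1.83 and -1.19, and of 1.28 and -2.27 in the kallisto-layout table. In both of these overlapping pairs the genes moved in opposite directions, so the ratio of a single member does not show a change of the locus. Nnt (ENSMUSG00000116207.1) had a log2 ratio of 1.91, against 0.27 in the kallisto-layout table. Nutf2 had 1.28, against -0.69 there. Gemin4 had -1.29 and Eif4a-ps4 -1.62, against -0.07 and -0.42 there. Rpl9-ps6 had a ratio of 1.03 and was listed at 0 in the kallisto-layout table, and Fam220a had -1.26, against -1.54 there.

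Several groups of genes moved together between the replicates. Marker lists of vessels and fat were lower in replicate 2: the median log2 ratio was -0.35 for adipocytes, -0.30 for endothelium and -0.22 for smooth muscle and pericytes, each at the 0 percentile of 10000 random lists matched on expression. Of 11 endothelial markers 9 were lower in replicate 2, led by the VEGF receptor Kdr at -0.79 (interval -0.94 to -0.63), Emcn at -0.60 and Cdh5 at -0.42, while Vwf stood at 0.11 and Cldn5 at 0.17. Of 10 adipocyte genes 9 were lower, among them Cidec at -0.49, Fabp4 at -0.38 and Adipoq at -0.37, with Cfd at 0.26. Kcnj8 (-0.63) and Rgs5 (-0.33) led the pericyte genes. Of the 10 genes of the smooth muscle and pericyte list 7 were lower, while Cnn1 stood at 0.33, Myh11 at 0.09 and Tagln at 0.07. Satellite cell markers (-0.27, percentile 0.95) and erythroid genes (-0.21, percentile 0.78) were also lower, the first with no such shift in the kallisto-layout table (-0.03) and inside the central 95% of random lists on deposited TPM (percentile 30.9), the second inside it at a minimum of 100 counts (-0.08, percentile 7.98). Fibroblast markers did not join them (0.08, percentile 97.3, and -0.08, percentile 82.5, on deposited TPM), and Col1a1 (0.33) and Col1a2 (0.36) were higher in replicate 2. Tenocyte markers were higher in replicate 2 by a median of 0.17 (percentile 99.6), with Kera at 0.81, and by 0.003 on deposited TPM (percentile 96.9, inside the central 95%).

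Immediate early genes were higher in replicate 2, with a median log2 ratio of 0.29 (percentile 100) and 13 of 16 members above 0. Over the 10 members with at least 100 counts the median was 0.18 (percentile 99.98). Myc (1.17), Atf3 (0.67), Fos (0.57), Btg2 (0.50) and Dusp1 (0.38) had counting intervals above 0, and Nr4a3 went the other way. The clock list had a median of 0.08 (percentile 99.3), and its members went both ways: Arntl, the core activator, stood at -0.79 (interval -1.08 to -0.52) and Nr1d1 at -0.32, whereas Ciart stood at 0.45, Per2 at 0.37 and Per3 at 0.31. Slow fibre genes were lower in replicate 2 by a median of -0.13 (percentile 0.04, 10 of 11 members), with Casq2 at -0.31 and Mybpc1 at -0.26. Fast fibre genes (0.09, percentile 99.9, 12 of 13 members above 0) and glycolysis genes (0.10, percentile 99.98, 14 of 15) lay on the other side, and Fbp2 at 0.55 had the highest ratio of the glycolysis list. The medians of the fast fibre, glycolysis and clock lists were -0.05, -0.05 and -0.07 on the deposited TPM scale, on which the median of all genes tested was -0.13 and the clock list lay inside the central 95% (percentile 92.8).

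**Figure D3:**
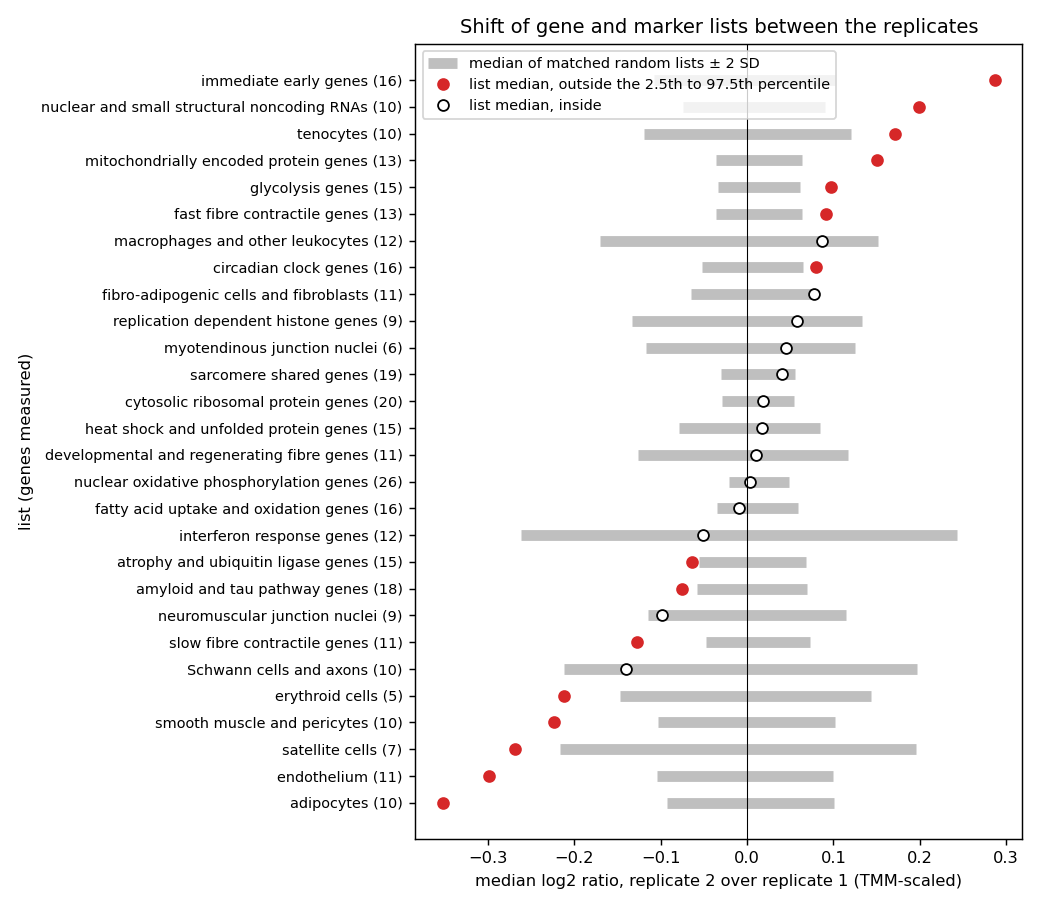
Median log2 ratio of replicate 2 over replicate 1 for each of the 28 lists, with the number of genes measured in brackets. Grey bars span the median of matched random lists ± 2 SD, and the 15 red points are lists outside the central 95% of random lists, from adipocytes at -0.35 to immediate early genes at 0.29.

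Other groups outside the fibre, vessel and clock lists were shifted too. The structural noncoding RNAs had a median of 0.20 (percentile 99.99), with Rian at 0.44, Meg3 at 0.35, Rpph1 at 0.33 and Rn7sk at 0.28. In the kallisto-layout table its median was 0.12 (percentile 99.5), Rn7sk stood at 0.11 and Rmrp at -0.17, against 0.08 for Rmrp in the RSEM table. Mitochondrially encoded genes had a median of 0.15 (percentile 100), which was 0.04 (percentile 84.2) in the kallisto-layout table. The amyloid and tau list had a median of -0.08 (percentile 0.81) with Clu at -0.25, Bace1 at -0.20 and App at -0.08, and a median of 0.02 under spike-in scaling. The atrophy list had -0.06 (percentile 1.53), with Fbxo30 at -0.41 and Trim63 at -0.21. Its median was 0.03 under spike-in scaling, and -0.03 (percentile 8.18, inside the central 95%) at a minimum of 100 counts. Lists inside the central 95% of random lists were oxidative phosphorylation (0.00, percentile 27.1), fatty acid use (-0.01, 15.6), shared sarcomere genes (0.04, 89.2), developmental fibre genes (0.01, 60), heat shock genes (0.02, 64.8), interferon genes (-0.05, 36.1), ribosomal proteins (0.02, 62.0), histones (0.06, 83.2), leukocytes (0.09, 89.1), Schwann cells (-0.14, 10), synaptic nuclei (-0.10, 4.67) and myotendinous nuclei (0.05, 77.2).

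The spread of external spike-in RNAs, which holds counting error and other technical spread together, was set beside that of genes. Of 96 ERCC RNAs, 62 had counts in both libraries, and they took 0.526% of expected counts in replicate 1 and 0.473% in replicate 2. Over the 26 with a mean count of at least 100, the SD of the log2 ratio was 0.133, where counting error alone gave 0.088 (95% of simulations 0.056 to 0.130) and genes of matched count gave 0.151 (0.095 to 0.242). Over the 15 with at least 500 counts the SD was 0.057, inside the range of counting error alone, 0.038 (0.023 to 0.060). Matched genes gave 0.095 (0.051 to 0.193). The spread of the spike-ins lay inside the range of matched genes at both minimums, so the larger spread of genes was not resolved at these numbers of spike-ins.

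Levels of some genes differed between the 2 quantifications, genes with copies in the genome among them. The RSEM gene table and the kallisto-layout table had a Pearson's r across genes of 0.970 in replicate 1 and 0.968 in replicate 2. Of 12348 genes with at least 1 TPM in either, 727 (5.89%) differed at least 2-fold in both libraries, 363 higher in the RSEM table and 364 higher in the other. Pseudogenes made up 315 of the 727, small and miscellaneous RNAs 133 and protein-coding genes 129. The share of each class among all 12348 genes was not computed. mt-Co2 was at 392 and 551 TPM in the RSEM table and at 2743 and 3392 TPM in the kallisto-layout table, and the pseudogene Gm28661 on chromosome 1 (24614885 to 24615565) was at 17372 ± 961 TPM in the RSEM table and at 14115 and 12877 TPM in the other, above mt-Co2 in both. mt-Co3 and Gm28437, and mt-Atp6 and Gm10925, are further pairs in which the pseudogene took the larger level in the RSEM table (14997 ± 1020 against 1804 ± 105 TPM and 15206 ± 224 against 5680 ± 518 TPM). In the kallisto-layout table the pseudogenes were the lower ones, Gm28437 at 8065 and 5090 TPM against mt-Co3 at 8071 and 9955 TPM, and Gm10925 at 337 and 691 TPM against mt-Atp6. The genes with the highest RSEM over kallisto-layout ratios were Gm12338 (797 ± 80.5 TPM against 0), Gm26447, Gm24265, Gm24407 and Gm22988, all listed at 0 in the kallisto-layout table. At the other end were Gm19220, listed at 0 in the RSEM table and at 2971 and 3627 TPM in the other, Rpl36a-ps3, Rpl17-ps3, Gm4459 and Gm26822.

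The leading transcript of a gene of at least 10 TPM was shared more often between libraries than between quantifications. Among 4163 genes of at least 10 TPM with several transcripts, the leading transcript was the same in both libraries for 92.5% in the RSEM table (exact 95% interval 91.6 to 93.2%) and for 3748 of them in the kallisto-layout table. Between the tables it was the same for 82.8% in replicate 1 and 82.0% in replicate 2. Of 17 muscle genes chosen beforehand, 14 had the same leading transcript in both tables by mean share, and 11 had one that held at least 50% of the gene's TPM in the RSEM table (10 in the kallisto-layout table). In the RSEM table Atp2a1-201 held 99.9 ± 0.07%, Tpm1-205 97.1 ± 0.21%, Tpm3-205 94.1 ± 0.31%, Ank1-208 83.6 ± 0.83%, Bin1-205 82.2 ± 1.16%, Ldb3-207 77.6 ± 0.08%, Myl1-202 74.0 ± 1.56% and Pdlim3-203 64.4 ± 0.49%. Pkm was split between Pkm-202 (55.9 ± 0.19%) and Pkm-201 (42.3 ± 0.04%), and Tnnt3 between Tnnt3-224 (53.9 ± 0.71%) and Tnnt3-201 (38.5 ± 0.20%), which the kallisto-layout table gave as 75.3 ± 1.83% and 10.7 ± 2.96%. Vegfa-202 held 51.2 ± 1.78% (45.9 ± 0.54% in the kallisto-layout table), Mef2c-201 46.9 ± 3.3%, Ppargc1a-203 45.5 ± 3.2%, Tpm2-202 45.3 ± 0.24% and Mef2d-201 43.0 ± 1.77%. The 3 genes whose leader differed were Tnnt1 (Tnnt1-203 at 36.8 ± 7.8%), Mbnl1 (Mbnl1-201 at 17.6 ± 0.05%) and Myl1. In the RSEM table the leader of Tnnt1 also differed between the libraries: Tnnt1-201 held 40.6% and Tnnt1-203 31.3% in replicate 1, and 27.7% and 42.3% in replicate 2. For Mbnl1, Mbnl1-214 (18.3%) stood above Mbnl1-201 (17.6%) in replicate 1 and below it in replicate 2 (16.5% against 17.5%). For Myl1 the kallisto-layout table gave 27.0 ± 2.78% to Myl1-202 and 46.1 ± 4.6% to Myl1-207, which had 0.075 ± 0.006% in the RSEM table.

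**Figure D4:**
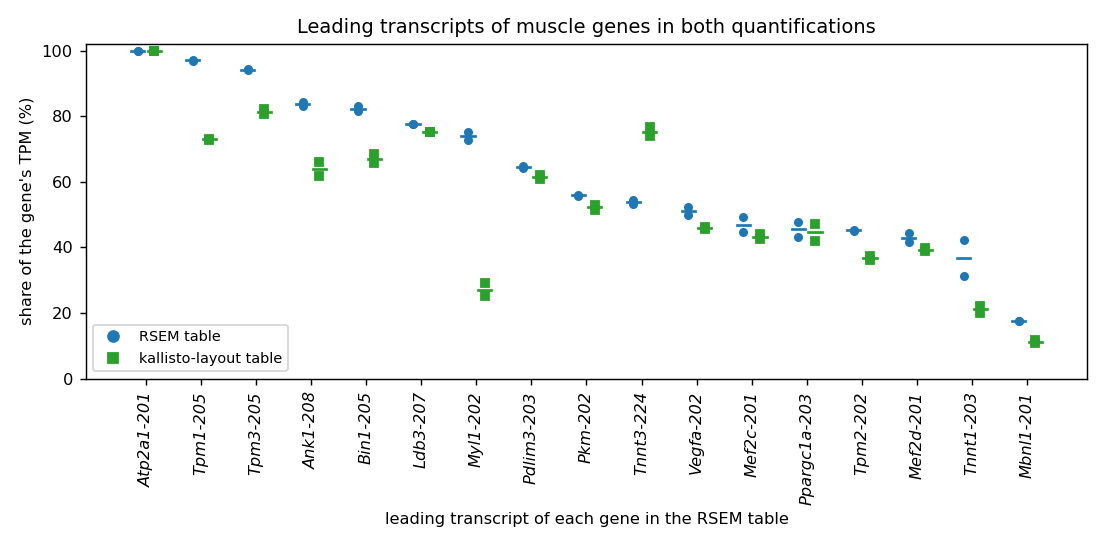
Share of the gene's TPM (%) held by the leading transcript of each of 17 muscle genes, in the RSEM table (blue circles) and the kallisto-layout table (green squares), with both libraries as points and their mean as a line. Atp2a1-201 is at 99.9% in each table, whereas Myl1-202 is at 74.0% in the RSEM table and 27.0% in the other.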

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

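The tests of the 2 patterns weighed here were chosen after their results were seen, except that of the second endothelial list, whose values had not been seen when it was written. A signal outside the main measurement was found in the rows for phiX, a bacteriophage used as a sequencing control: 245 expected counts in replicate 1 and 222 in replicate 2, against a limit of 3 counts that a count of 0 allows. These were 0.000693% and 0.000624% of all expected counts.

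Cish and Socs2 were higher in replicate 2. Both were picked from genes without divided reads, so reads shared with another gene had largely been set aside by that choice. The smaller ratio of the 2 genes in the kallisto-layout table was 1.04. Their smallest log2 ratio over 5 scalings was 0.82. Scalings that move all genes alike were too small to remove ratios of this size, so they were no test. A candidate explanation is a difference in cytokine or growth hormone signalling through STAT5, which induces both genes. Of 10 other measured STAT5-induced genes 6 were higher in replicate 2, with a median of 0.24 (percentile 99.7), among them Socs3 at 1.25, but 2 of the list also stand among the immediate early genes. Without Myc and Fos the percentile was 70.9, with Pim1 at -0.74 and Igf1 at -0.19 against Socs3, so the explanation stays open, and no biological explanation was tested by the design, which holds 1 group.

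Endothelial markers were lower in replicate 2. A second list of 16 endothelial genes with no member in common had 15 lower in replicate 2, among them Aqp1 at -0.30, Ptprb at -0.23 and Nos3 at -0.36, and its median of -0.22 stood at percentile 0.10. A lower share of endothelial RNA in replicate 2 may therefore be present, in a difference of sampled tissue or of vessels that the design cannot separate. An equal loss of all cells outside the fibres does not account for it, since fibroblasts, tenocytes and leukocytes were not lower. The median was 0.077 for fibroblasts (SD of random lists 0.04), 0.17 for tenocytes and 0.09 for leukocytes. The drop was not particular to endothelium. Adipocytes (-0.35), smooth muscle and pericytes (-0.22), satellite cells (-0.27) and erythroid genes (-0.21) were lower too, the last 2 not under every setting. A joint loss of several of these cell types was not excluded. On deposited TPM all genes had a median of -0.13. There fibroblasts (-0.083, percentile 82.5) lay within the range of their random lists, neither set apart above them nor lower. Size factors and totals move all genes alike and could not change the rank of endothelial markers among random lists. The endothelial median was -0.21 under spike-in totals, the highest of the 4 scaling alternatives. On deposited TPM, which can change the rank, the endothelial list stood at percentile 0.02.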

How the results depend on the processing

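The alternatives without divided reads were chosen after seeing the data, and all others before. Detection at 5 TPM gave 6922 genes per library, and single libraries gave 11240 to 11508 at 1 TPM. The fast share of myosin was 98.5% in the kallisto-layout table and 98.8% by counts, moves larger than its SD and small in size. The count of genes at 2-fold was 413 with a minimum of 10 counts, 5 with 500, 5397 with no minimum and 8 without divided reads, as low counts and divided reads make most of it. It was 27 to 41 under other scalings and the other prior. Deposited TPM gave 13 higher and 28 lower, and the kallisto-layout counts 18 higher and 8 lower, 13 of them among the main 29. Spike-in SD was 0.239 from 10 counts and 0.057 from 500, where counting error differs. The mitochondrial share was 19.5% of TPM and 16.8% of kallisto-layout counts. Genes differing between quantifications numbered 1603 with no minimum and 255 at 10 TPM, and Pearson's r was 0.963 with a pseudocount of 0.1. The leading transcript was the same for 85.6% of genes from 1 TPM, 96.6% from 50 TPM and 99.4% where it held 60%. From 1 TPM it was 82.7% between libraries in the kallisto-layout table, against 82.3% and 81.6% between the tables. Of the 15 lists outside the central 95% of random lists, 9 kept their side under all settings. The others fell inside on deposited TPM (clock, satellite and tenocyte genes), at a minimum of 100 counts (atrophy and erythroid genes) or in the kallisto-layout table (mitochondrial and satellite genes). Only these settings could change a percentile. DESeq2 size factors, library totals and spike-in totals shift all genes by the same amount and leave every percentile as it was. Schwann cell genes moved outside in the kallisto-layout table (percentile 2.22) and synaptic nuclei on deposited TPM (percentile 1.38). Among the 15 lists, medians changed sign on deposited TPM for fast fibre (-0.047), glycolysis (-0.052) and clock genes (-0.074), and under spike-in totals for atrophy (0.028) and amyloid and tau genes (0.016), since these scalings move all genes, by -0.13 and 0.09. Medians of lists inside the central 95% changed sign on deposited TPM too, among them fibroblasts (-0.083), shared sarcomere genes (-0.099), histones (-0.081) and myotendinous nuclei (-0.157). In the kallisto-layout table the ratio of Nutf2 was -0.69 and that of Gm14760 -0.035, and the cause was not tested. Of 527 alternatives for single lists, genes, classes and transcripts, 347 kept their result, 173 moved by more than the spread and 7 reversed. Reversal was scored only for gene ratios and for lists outside the central 95%, so sign changes of other lists count as kept or moved. Of 53 alternatives for the main answers, 36 kept their result and 17 moved. For levels, shares and correlations, 1 library alone lies within the SD of 2 libraries by construction, so these alternatives were no check. Low counts limit the ratios, and 2 libraries limit every SD.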

Other observations

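The lists of the next paragraph and all tests reported here were chosen after the data were seen. Genes of excitation and calcium release were expressed at a median of 194 ± 6.9 TPM over 14 genes. Casq1, the calcium store protein of fast fibres, stood at 1280 ± 25.1 TPM, the release channel Ryr1 at 844 ± 53.5 TPM, Trdn at 537 ± 10.6 TPM, the voltage sensor Cacna1s at 368 ± 9.8 TPM and the sodium channel Scn4a at 244 ± 14.3 TPM. The chloride channel Clcn1 was at 79.2 ± 1.27 TPM. Their median log2 ratio between the replicates was 0.04 (percentile 90.4). Genes of the dystrophin complex were lower, at a median of 37.7 ± 3.1 TPM, with Sgca at 128 ± 12.2 TPM, Dag1 at 65.4 ± 7.6 TPM and Dmd at 37.3 ± 3.3 TPM, and a median ratio of -0.01 (percentile 21.6).

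Among 12 genes of secreted muscle factors, with a median of 2.99 ± 0.37 TPM, Sparc (108 and 96.7 TPM in replicates 1 and 2), Ostn, which encodes musclin (41.1 ± 6.0 TPM), Mstn, which encodes myostatin (26.5 ± 1.05 TPM) and Fndc5 (20.7 ± 1.12 TPM) were the most abundant. Fgf21 had 0 counts in both libraries and Il6 had 1 and 0 counts, at or under the 3 counts that a count of 0 allows. The 9 members measured had a median ratio of -0.04 (percentile 20.6).

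Genes with ratios short of 2-fold and without divided reads included Chac1, an enzyme of glutathione breakdown, at 0.98 (interval 0.87 to 1.09), and Ighm, the immunoglobulin heavy constant mu gene, at 0.79 (0.72 to 0.87), both higher in replicate 2. The endothelial genes Adgrl4 (-0.78), Ets1 (-0.72) and Podxl (-0.65), named after their ratios were seen, were lower.

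Lars2, Gm26917 and Gm42418 were higher in replicate 2, with log2 ratios of 0.89, 0.40 and 0.40. More mRNA of the Lars2 gene is argued against by its full coding transcript Lars2-201, at 0.024 (interval -0.10 to 0.15), whereas its transcript annotated as a target of nonsense-mediated decay had 2686 and 5697 expected counts (1.14, interval 1.07 to 1.20). Of the words of 31 bases of this second transcript, 0 stand in 360 annotated ribosomal RNA, Gm26917 and Gm42418 transcripts. A first version with only the words absent from Lars2-201 also gave 0. This argues against reads that match these annotated transcripts exactly. Inexact matches and ribosomal RNA sequence outside the annotation were not searched, so ribosomal RNA as a whole was not excluded. For Gm42418 (chromosome 17, 39846958 to 39848788) a candidate explanation is residual ribosomal RNA. Of the gene, 68.0% lies inside Rn18s-rs5, a pseudogene of 18S ribosomal RNA by its RefSeq name, counted without regard to strand. A first version of this test, overlap on the same strand with annotated ribosomal RNA, gave 0 and was replaced. The annotated ribosomal RNA gene CT010467.1 (39846353 to 39848827) covers Gm42418 on the other strand and had 32 and 50 counts. The explanation was therefore not settled. What the reads of the second Lars2 transcript are stays open, and no biological explanation was tested.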
